A study of Mus musculus with 2 samples.

How the data were processed

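MicroRNA sequencing was deposited for 2 libraries labelled layer of hippocampus tissue, from male B6CASTF1/J mice aged 25 days. They were total RNA with a size range under 30 bases per the labels. For each library the authors deposited raw read counts per miRNA gene, with mm10 as the genome build and GENCODE M21 as the annotation per the text file deposited with it. The aligner, the counter and their versions are not given in the sources used here. Each table holds 3 deposited count columns, without regard to strand, on the strand of the gene and on the other strand, and opens with 4 rows that name no gene, for unmapped reads, reads aligned to several places, reads on no feature and ambiguous reads. Reads aligned to several places are thus held apart from the gene counts, which can lower the counts of genes with identical copies. No molecular identifiers are mentioned, so intervals and floors cover counting error only.

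All 2202 gene identifiers matched the miRNA genes of GENCODE M21 (GRCm38, the same assembly as mm10), from which symbols, coordinates, host genes and precursor sequences were taken. A gene was called intronic or exonic by a host gene on the same strand that contains it, with protein-coding and then shorter hosts preferred. The count column on the gene's strand was used, since it held 5183641 and 5871233 counts against 302866 and 387741 on the other strand, and the 4 rows without a gene were left out of library sizes. In replicate 1 and replicate 2, these rows were 14.1% and 15.5% of reads for unmapped reads, 43.6% and 43.2% for reads aligned to several places, and 5.04% and 4.59% for reads on no feature. The column on the gene's strand had no ambiguous reads, while the unstranded column had 302690 and 387518.

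Counts were scaled to CPM of the gene-assigned total, and log2 values carry a pseudocount of 1. A gene was called detected with at least 10 counts in both libraries, and libraries were compared over genes with a mean count of at least 10. With 1 group there is no coefficient for a quasi-likelihood test, so edgeR 4.0.16 (R 4.3.3) gave only the common dispersion with an intercept and TMM scaling, and DESeq2 1.42.0 an alternative dispersion and size factors. Differences between the libraries were tested per gene with a 2-sided exact binomial test against the library's share of the total, with Benjamini-Hochberg adjustment, and over all genes with a chi-square test (scipy 1.17.1). Intervals are exact Clopper-Pearson intervals at 95%. Lists were compared with 10000 random lists of the same size, drawn from detected genes for levels and from the 50 genes nearest in mean expression for differences. Counts of list members were given both adjusted over all genes tested and adjusted over the list alone. Multi-copy genes were those sharing 20 bases on either strand with a miRNA gene at another place, which can also be met by relatives that differ within the mature sequence.

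The binomial test and the dispersion were tested on simulated data drawn from these libraries' means and sizes. Of 467 genes in that step, the test recovered 37 of 70 genes changed 1.25-fold, 56 of 64 changed 2-fold and 56 of 57 changed 4-fold, and called 5 of 276 unchanged genes. In that step read sampling was the only noise, and the known totals were used for scaling. The rates therefore do not hold for these libraries, whose biological coefficient of variation was 0.320. A simulated coefficient of variation of 0.3 over 472 genes was estimated as 0.315.

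The design, the 12 lists, the rule for naming genes and all but 3 of the kinds of alternative were set before the data were examined. The text names the 25 genes with the highest mean CPM, the 3 highest members of each list, and the 5 highest and 5 lowest log2 ratios among genes with a mean count of at least 100 that passed the binomial test. Other genes named, such as Mir124a and the let-7 copies, were chosen after their values were seen. Alternatives covered the count minimum, the strand column, the scaling, the pseudocount, the correlation measure, the stretch length, multi-copy genes and each library alone. With 2 libraries of 1 group, no comparison between groups, paired analysis or regrouping of samples could be made.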

Results

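Small RNA was profiled by microRNA sequencing in 2 libraries from male mice at 25 days of age. The tissue is labelled layer of hippocampus and is called hippocampus below. The mice were of the B6CASTF1/J strain, first-generation hybrids of the C57BL/6J and CAST/EiJ inbred strains. The labels name the libraries biological replicates 1 and 2 of 1 group and give them separate biosamples but 1 shared donor entry, so the spread between them is the spread between these samples and may be partly technical. No treatment, genotype or second tissue was included. The comparisons the design allows are therefore the levels of the microRNA (miRNA) genes against each other and the difference between the 2 libraries. Replicate 1 held 5183641 reads assigned to a miRNA gene on its own strand, which was 37.3% of its 13900596 reads, and replicate 2 held 5871233, which was 36.7% of 15995194. At these depths a count of 0 allows a level of up to 0.579 counts per 1000000 gene-assigned counts (CPM) in replicate 1 and 0.511 CPM in replicate 2, for counting error only.

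Which miRNA genes did the juvenile hippocampus express? Of 2202 annotated miRNA genes, 445 (20.2%) had at least 10 counts in both libraries, 105 had a mean of 1000 CPM or more, and 1401 had no count in either. With a minimum of 100 counts, 268 were detected. These levels and ranks cover only reads assigned to a gene. Reads aligned to several places, 43.6% of reads in replicate 1 and 43.2% in replicate 2, are left out. Genes with identical copies may therefore rank too low. The gene-assigned counts were concentrated in few genes. The 10 most abundant took 54.6% ± 1.59 of the gene-assigned counts (SD, n = 2) and the 25 most abundant took 73.0% ± 1.95. The highest mean was that of Mir139 (ENSMUSG00000065446.1), which lies in an intron of the phosphodiesterase gene Pde2a on chromosome 7, from 101475376 to 101475443 on the plus strand of mm10, at 116379 ± 3992 CPM (SD, n = 2). Mirlet7b (ENSMUSG00000065564.1), in an exon of the noncoding gene Lncppara on chromosome 15 from 85707319 to 85707403, followed at 112671 ± 3489 CPM. Mir139 was above Mirlet7b within both libraries, by 3708 ± 502 CPM (SD of the gap, n = 2). Mir127 (ENSMUSG00000070076.2), on chromosome 12 from 109592846 to 109592915, came next at 65791 ± 23670 CPM. Its library values were 82528 and 49054 CPM.

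Mirlet7g had 60490 ± 4321 CPM and Mirlet7i 53434 ± 111 CPM. Mir744, in an intron of Map2k4, had 37086 ± 6106 CPM, and Mir99a, in an intron of its noncoding host gene, had 28653 ± 9508 CPM. Mirlet7e (24865 ± 3729 CPM), Mirlet7d (24546 ± 12336 CPM) and Mir770 (21690 ± 1797 CPM), in an exon of the imprinted noncoding gene Meg3, completed the leading 10. Ranks 11 to 25 ran from Mir23b at 19108 ± 4350 CPM to Mir125a at 8342 ± 1469 CPM. In order they were Mir23b, Mir433, Mir487b, Mir132, Mir382, Mir99b, Mir652, Mir191, Mir324, Mir330, Mir151, Mir328, Mir541, Mir92b and Mir125a. Of the 24 pairs of neighbouring ranks, 9 had the same order in both libraries. Mir99a, Mirlet7e and Mirlet7d stood in opposite orders in the 2 libraries. Relative to the mean, the smallest SDs among the 25 were those of Mir652 (0.153% of 11212 CPM), Mirlet7i (0.208%) and Mir151 (0.612% of 9878 CPM), and the widest was that of Mir99b (89.1% of 11683 CPM). Which SDs were smallest depends on the scaling to the gene-assigned total. The log2 ratios of Mir652, Mirlet7i and Mir151 were 0.003, 0.004 and 0.012, and TMM scaling shifts every log2 ratio by -0.17.

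**Figure D1:**
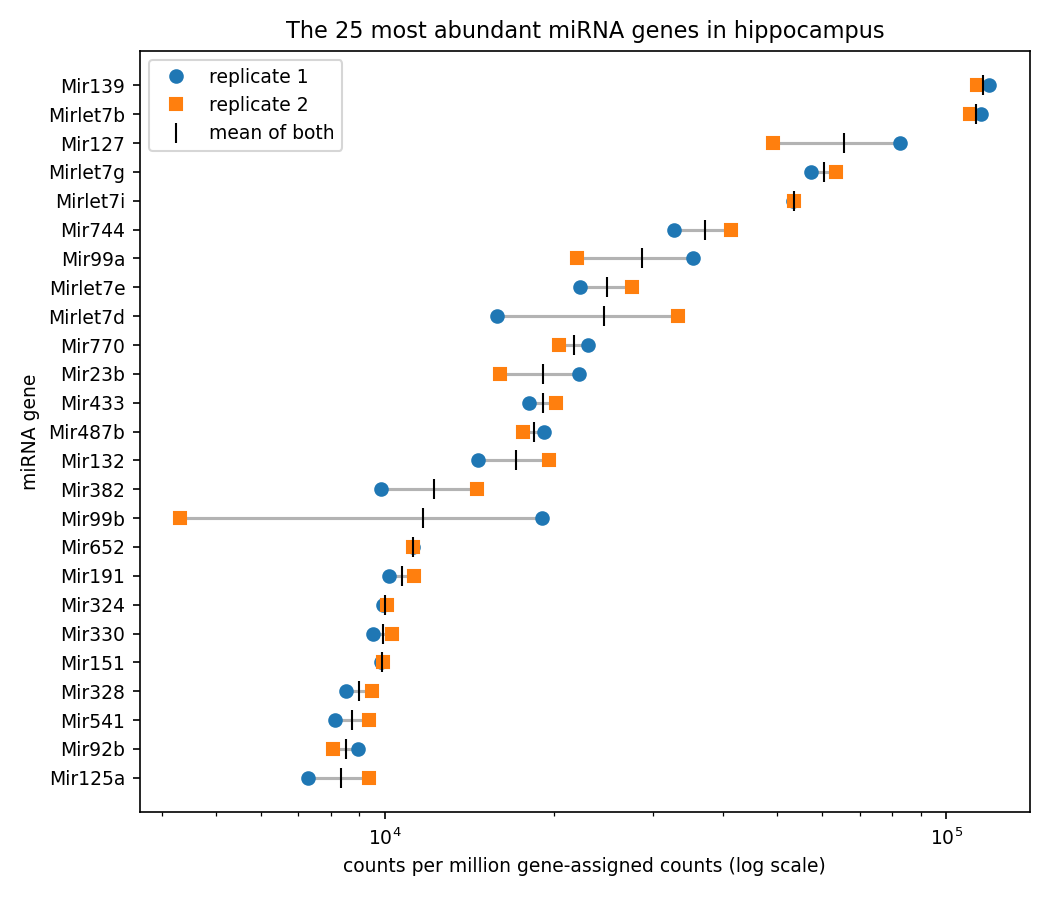
Level of the 25 most abundant miRNA genes, in CPM on a log axis. The circle is replicate 1, the square replicate 2 and the vertical tick their mean; the grey line joins the libraries. Mir139 (113557 and 119202 CPM) and Mirlet7b (110204 and 115138 CPM) lie highest in both libraries, and Mir99b has the longest line, from 4319 to 19048 CPM.

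Families and genomic clusters were compared as 12 fixed lists that share no member. The let-7 family, which restrains growth and stem cell programmes in differentiated tissue, took the largest share of counts at 28.5% ± 1.84 (SD, n = 2), and all 12 of its members were detected. The imprinted Dlk1-Dio3 clusters of chromosome 12, expressed from the maternal chromosome, took 19.2% ± 1.90, with 48 of 51 members detected. Their highest members were Mir127, Mir770 and Mir433 (19080 ± 1478 CPM). The median detected Dlk1-Dio3 member had 827 CPM, above that of all 10000 random lists of 48 detected genes (percentile 100), and the let-7 median of 2870 CPM lay at percentile 99.95. The Mir17 cluster and its paralogous clusters, active in proliferating cells, took 0.471% ± 0.0197, led by Mir93 (2212 ± 315 CPM), Mir17 (1093 ± 62.8 CPM) and Mir92-1 (665 ± 72.7 CPM). The Mir297, Mir466, Mir467 and Mir669 genes, of which 71 of 81 lie in the gene Sfmbt2, took 0.199% ± 0.0161. Of these 81 genes 8 were detected, led by Mir467d (907 ± 41.1 CPM), Mir669c (490 ± 37.2 CPM) and Mir467e (263 ± 42.6 CPM), and 79 of the 81 share a 20-base stretch with another miRNA gene, without which the share was 0%. With the multiply aligned reads added to the total but credited to no list, the let-7 share was 13.1% and that of Dlk1-Dio3 8.85%, and the other lists were lowered by about the same factor. Any such reads from a list's own genes are thus missing from its share.

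Lists of cell type markers gave the following makeup of the gene-assigned counts. Reads aligned to several places are left out of them. In the neuron-enriched list 15 of 21 genes share 20 bases with a gene elsewhere, and in the astroglia-associated list 7 of 9 do. The order of these shares is therefore uncertain. Neuron-enriched miRNA genes took 4.10% ± 0.229 of counts (SD, n = 2), with 18 of 21 detected. They were led by Mir132, a miRNA induced by neuronal activity, at 17116 ± 3460 CPM, Mir128-1 at 6294 ± 123 CPM and Mir138-1 at 5856 ± 1194 CPM. The astroglia-associated list took 3.12% ± 0.513, led by Mir23b, Mir23a (5093 ± 2273 CPM) and Mir29a (3939 ± 329 CPM). The oligodendrocyte list, of miRNAs that promote myelinating cell differentiation, took 0.596% ± 0.101. Its members Mir219a-2 (4230 ± 677 CPM) and Mir338 (1728 ± 326 CPM) carried it, and Mir219a-1 had 5.64 ± 5.52 CPM. Endothelium and vessel wall genes took 0.905% ± 0.0367, from Mir126a in the endothelial gene Egfl7 (5574 ± 389 CPM), Mir143 (3167 ± 518 CPM) and Mir145a (312 ± 238 CPM). Without the genes that share 20 bases with a copy elsewhere, the shares were 2.23% for neuron-enriched, 0.502% for astroglia and 0.173% for oligodendrocyte genes and stayed at 0.905% for vessel genes, so the astroglia share then lay below the vessel share. The medians of the detected neuron-enriched, astroglia, oligodendrocyte and vessel members lay at percentiles 95.5, 96.8, 95.5 and 97.0 of random lists of the same size. Detected were 18 of 21, 9 of 9, 2 of 4 and 3 of 4 members, and members below the detection minimum, such as Mir219a-1, do not enter these medians.

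Markers of other cells took smaller shares. The microglia and leukocyte list took 0.172% ± 0.00334 of counts (SD, n = 2), with Mir150 at 1075 ± 153 CPM, Mir146 at 572 ± 145 CPM and Mir142 at 35.2 ± 17.7 CPM. The choroid plexus and ciliated epithelium list took 0.130% ± 0.0161, with Mir204 at 608 ± 68.8 CPM, Mir34c at 505 ± 134 CPM and Mir449a at 99.7 ± 21.3 CPM. Red blood cell genes took 0.00494% ± 0.00106, and Mir486 (21.8 ± 1.92 CPM), Mir451a (21.8 ± 6.27 CPM) and Mir144 (5.77 ± 2.43 CPM) were all detected. The list of muscle, liver and pancreas took 0.0374% ± 0.00224, with Mir375 at 219 ± 39.9 CPM, Mir206 at 109 ± 46.0 CPM and Mir122 at 28.3 ± 11.1 CPM. The percentiles of these 4 list medians were 42.4, 27.0, 32.5 and 15.7, over the detected members only (5 of 5, 8 of 12, 3 of 3 and 6 of 14). A share of counts is not a share of cells, and the lists were not tested against each other.

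**Figure D2:**
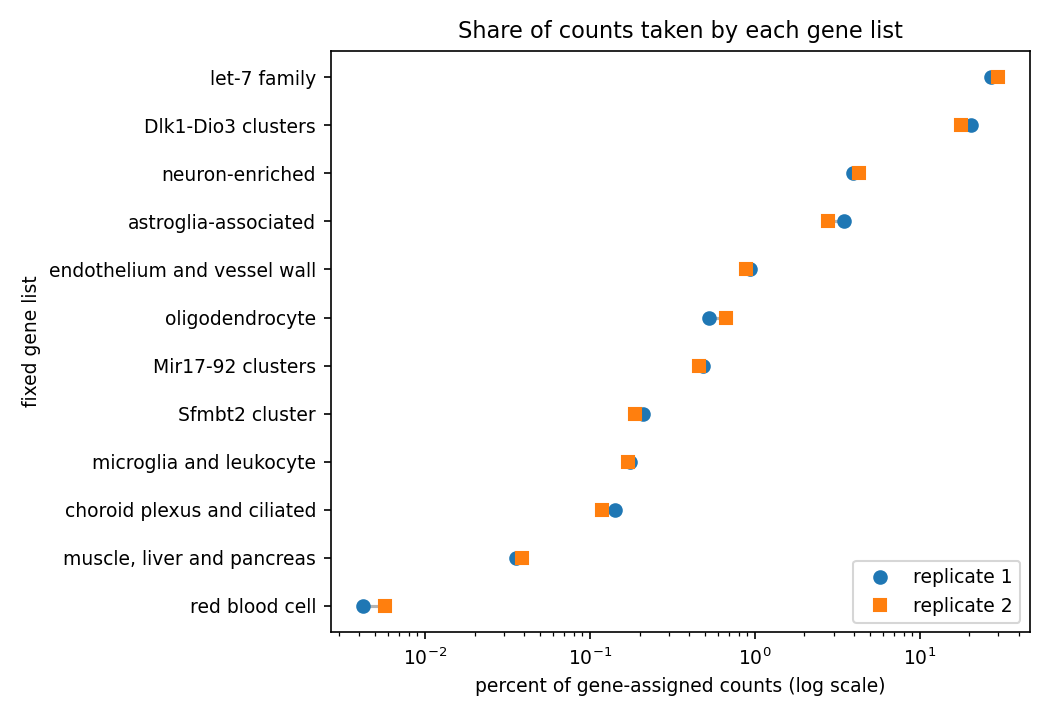
Percent of gene-assigned counts taken by each of the 12 fixed gene lists, on a log axis, with replicate 1 as circles and replicate 2 as squares. The let-7 family (28.5% on average) and the Dlk1-Dio3 clusters (19.2%) lie far to the right of the red blood cell list (0.00494%), and the 2 libraries lie close together on each line.

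How alike were the 2 libraries? The genes that differed most were a pair of gene copies. Mir26a-2 was 13.7-fold higher in replicate 2 (95% exact interval of the counts 11.7 to 16.1), at 443 against 32.4 CPM, whereas Mir26a-1 was 7.36-fold higher in replicate 1 (5.62 to 9.78), at 77.7 against 10.6 CPM. Both are copies of 1 miRNA, in host genes of the Ctdsp phosphatase family, and share a stretch of 25 bases, so their levels are uncertain. Mir22 was 5.52-fold higher in replicate 2 (5.41 to 5.63), with 70507 against 11285 counts. The miRNA gene mmu-mir-3535 was 5.08-fold higher there (3.92 to 6.67), Mir101a 4.12-fold (3.46 to 4.93) and Mir340 3.99-fold (3.37 to 4.74). Higher in replicate 1 were Mir185 by 5.88-fold (5.53 to 6.26), Mir99b by 4.41-fold (4.35 to 4.47), Mir145a by 3.35-fold (3.09 to 3.62) and Mir543 by 2.43-fold (2.35 to 2.52). These are the 5 highest and 5 lowest log2 ratios among the genes with a mean count of at least 100. The intervals cover counting error only, under scaling to the gene-assigned total. TMM scaling shifts every log2 ratio by -0.17, which moves the folds with narrow intervals, such as those of Mir22 and Mir99b, outside them.

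Most genes lay close to each other in the 2 libraries. Across the 445 detected genes, log2(CPM + 1) correlated with a Pearson r of 0.985 and a Spearman rho of 0.977, values across genes, which are not independent replicates. A chi-square test over 472 genes with a mean count of at least 10 gave 665 per degree of freedom, so the libraries differed by far more than sampling noise and were not 1 library deposited as 2. The common biological coefficient of variation, estimated with edgeR, was 0.320. Of 291 genes with a mean count of at least 100, 72.9% differed by less than 1.5-fold, the median absolute log2 ratio was 0.34, and 34 differed by 2-fold or more.

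In an exact binomial test of the counts, 282 of 472 genes (59.7%) differed between the libraries by more than read sampling at a Benjamini-Hochberg adjusted p below 0.05, 186 higher in replicate 2 and 96 higher in replicate 1. At least 2-fold apart were 66 of them, 45 higher in replicate 2 and 21 in replicate 1. The split of directions depended on the scaling. With scaling by trimmed mean of M-values (TMM), which shifts every log2 ratio by -0.17, 141 genes were higher in replicate 2 and 137 in replicate 1. This test compares 2 libraries and takes reads as independent molecules. It leaves out the spread between samples, so these calls and the counts of list members that rest on them do not show a difference beyond that spread.

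**Figure D3:**
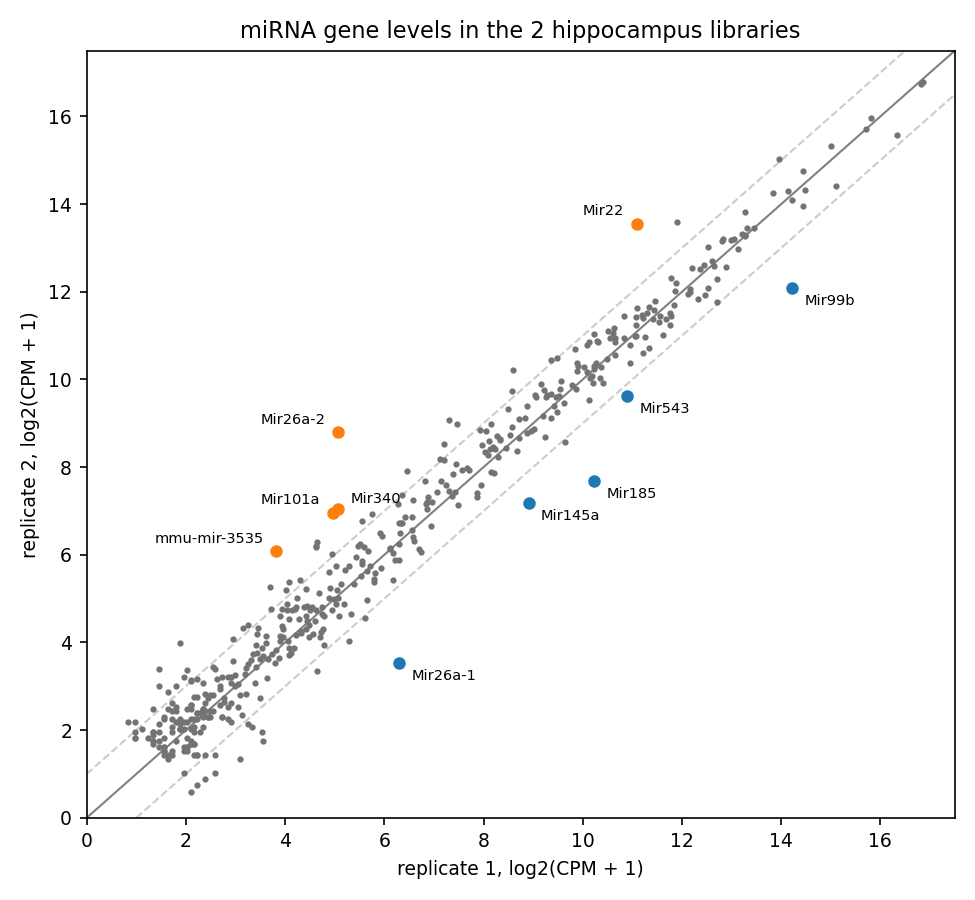
Level of each of the 472 miRNA genes with a mean count of at least 10, as log2(CPM + 1), in replicate 1 (x axis) and replicate 2 (y axis). The solid line marks equal levels and the dashed lines a 2-fold difference; orange points are the 5 highest ratios and blue points the 5 lowest, with Mir26a-2 and Mir26a-1 farthest from the line on either side.

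The list medians, over members with a mean count of at least 10, stand against a median log2 ratio of 0.17 over the 291 genes with a mean count of at least 100. Astroglia-associated genes had a median log2 ratio of replicate 2 over replicate 1 of 0.46, with 7 of 9 members higher in replicate 2 and 2, Mir23a and Mir23b, higher in replicate 1. The oligodendrocyte list had a median of 0.39 with 3 of 3 higher, let-7 a median of 0.23 with 8 of 12 higher and 1 lower, and Dlk1-Dio3 a median of 0.21 with 29 of 48 higher and 11 lower. The red blood cell list had a median of 0.57 with 2 of 3 higher, the choroid plexus list 0.27 with 2 of 9 higher and 3 lower, the muscle, liver and pancreas list 0.54 with 3 of 7 higher and 1 lower, and the Mir17 clusters 0.31 with 4 of 11 higher and 5 lower. The medians were -0.11 for neuron-enriched genes (4 of 18 higher, 9 lower), -0.32 for microglia and leukocyte genes (1 of 5 higher, 2 lower), -0.33 for vessel genes (1 of 3 higher, 2 lower) and -0.34 for the Sfmbt2-type genes (0 of 8 higher, 6 lower). Members not counted did not pass the test. Adjusted over the list alone, 108 of the 136 members compared differed, against 106 adjusted over all genes tested, and the microglia and leukocyte list changed from 3 to 5 of 5. In 5 lists the share of counts went the other way from the median. From replicate 1 to replicate 2 the share of astroglia-associated genes was 3.49% and 2.76%, of Dlk1-Dio3 genes 20.6% and 17.9%, of choroid plexus genes 0.142% and 0.119%, of Mir17 cluster genes 0.485% and 0.457%, and of neuron-enriched genes 3.94% and 4.27%. Against 10000 random lists matched on mean expression, the medians lay at percentile 0.38 for the Sfmbt2-type genes, 2.26 for neuron-enriched, 3.09 for microglia and leukocyte and 6.76 for vessel genes. The others lay at 60.5 for choroid plexus, 71.3 for Dlk1-Dio3, 71.5 for the Mir17 clusters, 76.5 for let-7, 83.5 for red blood cells, 85.9 for oligodendrocytes, 91.4 for muscle, liver and pancreas and 95.9 for astroglia-associated genes. These percentiles describe 12 lists in these libraries and are no test. No list median changed sign under TMM or DESeq2 scaling, but under TMM those of let-7 and Dlk1-Dio3 were 0.06 and 0.04 and those of astroglia-associated and neuron-enriched genes 0.29 and -0.28. With a minimum of 100 counts, the median of the Mir17 clusters changed sign to -0.17, and that of muscle, liver and pancreas was 0.79.

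Of the 1087 genes that share a 20-base stretch with a miRNA gene elsewhere, 7.91% were detected, against 32.2% of the 1115 that do not, and the sharing genes took 9.85% ± 0.889 of counts (SD, n = 2). That share depended on the length asked for, at 33.1% ± 0.885 with a stretch of 18 bases and 4.16% ± 0.0648 with 22 bases. The median log2(CPM + 1) was 0 for the sharing genes in both libraries, and 0.25 in replicate 1 and 0.42 in replicate 2 for the others. Restricted to genes with a Mir symbol outside the Sfmbt2-type list, the detected shares were 41.4% of 181 and 38.3% of 912, and with 22 bases 38.7% of 150 and 38.8% of 943, so the difference among all genes did not hold in this subset at these lengths. By the longest stretch shared, in ranges chosen after seeing the data and not tested, 38.1% of 893 genes were detected under 18 bases, 50% of 42 at 18 to 20, 65.8% of 38 at 21 to 23 and 31.7% of 120 at 24 or more. The copies of the neuronal miRNA miR-124 were nearly without counts. Mir124a-1 had 16 and 12 counts, Mir124a-2 had 0 and 1, and Mir124a-3 had 2 and 9, and they share a stretch of 32 bases. In both libraries more reads aligned to several places than were assigned to miRNA genes, with 6059074 such reads in replicate 1 (43.6% of reads, exact 95% interval 43.56 to 43.61) and 6908203 in replicate 2 (43.2%, 43.165 to 43.21). Levels of multi-copy genes named here, such as Mir128-1, Mir138-1, Mir219a-2, Mir92-1 and Mir146, are therefore uncertain.

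Reads fell on the annotated strand of a miRNA gene with few exceptions. Counts on the opposite strand summed to 5.52% of both strands in replicate 1 (exact 95% interval 5.50 to 5.54) and 6.19% in replicate 2 (6.18 to 6.21). Nearly all of these counts were reads that also stood in the sense column of an overlapping gene. The shares thus do not measure reads off the annotated strand. Without the 10 most abundant genes the shares were 11.6% and 12.4%. That setting removed the sense counts of Mirlet7e but kept the same reads, 115221 and 161468, on Gm25927, which overlaps it on the other strand. The rise therefore comes from the smaller sense total. Of the opposite-strand counts, 99.94% in each library lay on genes that overlap another miRNA gene on the other strand. They numbered 302690 in replicate 1 and 387518 in replicate 2, the same as the ambiguous reads of the unstranded column. Elsewhere 176 and 223 opposite-strand counts remained. In the column that ignores strand, the share of the oligodendrocyte list was 0%, that of red blood cells 0.000616% and that of vessel genes 0.371%.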

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

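The ratio across Mir-named genes was set before its own value was seen, on a restriction to Mir symbols chosen after seeing the data, and the other tests in this part were chosen after the values had been seen.

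Reads aligned to several places stand outside the gene counts and exceed them in both libraries, at 6059074 in replicate 1 and 6908203 in replicate 2, or 1.17 and 1.18 per gene-assigned count. They stand beside low counts of Mir124a (at most 16), Mir9-2 (4 and 11 counts) and Mir9-1 (71 and 68 counts), with Mir9-3 higher at 549 and 388, although miR-124 and miR-9 are known as abundant brain miRNAs. Within the let-7 family, the 6 genes that share 20 bases with a copy elsewhere (the let-7a, let-7c and let-7f genes) had 93.3 to 2597 CPM, and the 6 that do not had 3171 to 112671 CPM. The ratio of the medians was 0.0129, which describes the family but decides nothing, since it was picked after its low copies had been seen. In this ratio and those that follow, 0.5 CPM was added to each median. Across all Mir-named genes outside the Sfmbt2-type list the ratio of the medians of sharing and other genes was 0.675 (bootstrap interval 0.484 to 1.67). Those medians were 0.278 and 0.653 CPM, about the level that a count of 0 allows (0.579 CPM in replicate 1 and 0.511 CPM in replicate 2). The added 0.5 CPM therefore weighs heavily in that value. Within the neuron-enriched list the ratio was 0.501 (exact permutation p = 0.710). Both ratios pool many genes, so they cannot decide about Mir124a or about the let-7 copies, which were all detected. By the layout of the counts, a read lying wholly within a stretch shared by copies aligns to several places and is given to no gene. How many such reads came from these genes is undecided, because the multiply aligned reads carry no gene names. The low counts of Mir124a thus do not show absence from this tissue, which stays undecided.

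Counts on the strand opposite to the gene were not used in the comparisons and reached 302866 in replicate 1 and 387741 in replicate 2, far above the 3 counts that a count of 0 allows. The mean share of them on the 64 genes that overlap a miRNA gene on the other strand was 99.94%, as reads of a gene counted for its partner would give. Gm25927, for instance, had as many opposite-strand counts (115221 in replicate 1) as Mirlet7e, which it overlaps, had sense counts, and in the unstranded column Mirlet7e, Mir191, Mir219a-2 and Mir338 had 0 counts in both libraries. Away from overlapping genes 176 and 223 opposite-strand counts remained, or 34.0 and 38.0 per 1000000 gene counts, and no biological explanation was tested.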

How the results depend on the processing

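All settings here were planned except the share with multiply aligned reads in the total, the restriction to Mir symbols and the scaling without the 10 most abundant genes, which were added after seeing the data. The number of detected genes was 268 with a minimum of 100 counts, and 419 to 662 with the other minimums and the unstranded column. Replicate 1 alone gave 462 detected genes and a share of 55.7% for the 10 most abundant genes, and replicate 2 alone gave 491 and 53.4%; that share was 57.6% in the unstranded column. The correlation was 0.988 without a filter, 0.977 with a minimum of 100 counts and 0.977 as Spearman's rho. Of the genes differing between the libraries, 66 were also 2-fold apart; scaling and filters gave 242 to 284, with 141 higher and 137 lower in replicate 2 under TMM and 132 and 142 under DESeq2 size factors. The coefficient of variation stayed between 0.317 and 0.335. In the unstranded column the shares were 0% for the oligodendrocyte list, 0.000616% for red blood cells and 0.371% for vessels, because Mir219a-2, Mir338, Mir486, Mir451a and Mir126a overlap a miRNA gene on the other strand and their reads count there as ambiguous; they were 0.180% for microglia and leukocytes, 0.0398% for muscle, liver and pancreas and 0.502% for the Mir17 clusters. Without multi-copy genes they were 2.23% for neuron-enriched, 0.173% for oligodendrocyte, 0.502% for astroglia, 0.115% for microglia and leukocyte, 16.7% for Dlk1-Dio3, 0% for Sfmbt2 and 0.402% for Mir17 cluster genes. With multiply aligned reads in the total, the shares were 1.89% (neuron-enriched), 0.274% (oligodendrocyte), 1.44% (astroglia), 0.0791% (microglia and leukocyte), 0.00227% (red blood cell), 0.417% (vessel), 0.0599% (choroid plexus), 0.0172% (muscle, liver and pancreas), 13.1% (let-7), 8.85% (Dlk1-Dio3), 0.0916% (Sfmbt2) and 0.217% (Mir17 clusters), by the larger total alone. The let-7 share was lower in the unstranded column, at 27.7% against 28.5%, with Mirlet7e at 0 counts there. The other unstranded shares were higher because the total is smaller there, at 4881127 and 5483938 counts. The cause of the changes in the correlation was not tested. List medians of the log2 ratio moved by less than the SD over members in every setting, and the sign of 1 changed, the Mir17 clusters to -0.17 with a minimum of 100 counts. The opposite-strand share was 12.03% without the 10 most abundant genes, which took out their sense counts and almost no opposite-strand counts. Of the sharing genes 41.4% were detected when restricted to Mir symbols outside the Sfmbt2-type list, and 8.37% and 6.69% of all genes with stretches of 18 and 22 bases. The spread used to judge a change was the SD over list members for list medians, the 95% interval over genes for the correlation, and 1.5 times for the coefficient of variation. At these depths genes with few counts, such as Mir124a, limit what a ratio can show. Leaving out a library gave no value for comparisons between the 2 libraries. No paired analysis was possible because there is 1 group.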

Other observations

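The tests of clusters and of cell type lists, the mean without the Mir26a pair, the GC content, the clusters named and the shares by host and chromosome were chosen after the values had been seen.

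Most of the hippocampal miRNA counts came from genes lying within an annotated host gene on the same strand, coding or noncoding. Genes in introns took 44.7% ± 0.992 of counts (SD, n = 2), genes overlapping exons 33.3% ± 2.59, and intergenic genes 21.98% ± 1.59. Protein-coding hosts accounted for 43.2% ± 0.721 and lincRNA hosts for 11.4% ± 1.74. By chromosome, chromosome 12 contributed the most, 19.7% ± 1.99, with 63 of its 146 genes detected, followed by chromosome 15 (13.5% ± 0.162) and chromosome 7 (13.4% ± 0.234). The X chromosome gave 3.76% ± 0.132 from 38 detected genes. The 1028 annotated genes without a Mir symbol took 0.0999% ± 0.0169, and 13 of them were detected.

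Some neighbouring genes on the same strand parted between the libraries. In the cluster of Mir99b, Mirlet7e and Mir125a on chromosome 17 the log2 ratios of replicate 2 over replicate 1 were -2.14, 0.31 and 0.36. On chromosome 8, Mir23a, Mir27a and Mir24-2 had -0.94, 1.21 and 0.83, and on chromosome 13 their relatives Mir23b, Mir27b and Mir24-1 had -0.47, 0.72 and 0.53. Mir145a and Mir143, neighbours on chromosome 18, had -1.74 and -0.33. Mir106b had 1.77 while Mir93 had -0.29.

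Explanations were weighed for these gene-specific differences. Over 34 clusters with 126 genes (same strand, within 10 kb), the intraclass correlation of the log2 ratio was 0.0297 (95% bootstrap interval -0.17 to 0.18), which argues against a difference in transcription of the loci as the whole cause, since members of 1 transcript would then move together. For a difference in cell makeup, the intraclass correlation within 7 cell type lists was 0.198 (interval 0.04 to 0.61), which alone did not exclude it; the argument against it as the whole cause rests on the cluster value, a criterion added after the list value was seen, and on the assumption that cells bring all members of a transcript. Capture that depends on the miRNA sequence, such as adapter ligation, may differ between library preparations. The mean product of standardized ratios over 104 pairs of genes at other places that share 12 bases was -0.0811 (interval -1.28 to 0.42, permutation p = 0.813), which leaves such capture open. Without the pair of Mir26a-1 and Mir26a-2 that mean was 0.14, so 1 pair decides its sign. Over the 72 pairs whose genes do not both share 20 bases with a gene elsewhere, the mean was 0.06. In the other pairs, reads of a shared stretch can be missing from the counts, so those pairs cannot test its capture. Differences in processing or stability of single miRNAs remain open and untested.

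The GC content of the precursor accounted for 0.811% of the variance of the log2 ratio across 291 genes (Pearson r = -0.09).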
